A study of Brassica rapa subsp. chinensis with 24 samples.

How the data were processed

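Polyadenylated RNA of whole leaves and whole roots was sequenced as paired-end reads of 100 bases, per the labels' protocols, from SAB-treated and untreated plants of day 8 and day 18, with 3 independent biological replicates in each of 8 groups. Trim Galore, Bowtie2 and kallisto are named in the submitters' processing notes; their roles, versions, the transcript index and its annotation are not given in the sources used here. The authors deposited 1 table of estimated counts with 66566 rows and 24 libraries, with totals of 28068078 to 37999455 per library, and no other columns of per-sample values. The deposited estimated counts are not whole numbers (0.99% of the values above 0 are whole), so they were rounded to whole numbers before each count test.

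The low values of a row lay near multiples of a step of that row's own, nearly the same in every library: 71.8% of the values of 8182 low rows lay within 0.1 step of a whole multiple, against 35.1% after random scaling. The step had a median of 6.21 units, with a 5th percentile of 3.32 and a 95th percentile of 15.46. These rows were chosen with a highest value below 60 units and a lowest value above 0 of more than 3 units. Steps under about 3 units were thus left out in advance, and large steps were limited. In these rows the deposited values thus behave like abundance divided by feature length and scaled back to the library total. There 1 read is worth more than 1 unit, and how many other rows have smaller steps was not measured. A floor of 3 reads per library was taken at the 95th percentile of these steps as 46.4 units, or 1.32 to 1.5 CPM in the comparisons that use it. A fold against a group at 0 in all its libraries is given as a lower bound against this floor, which covers counting error only. The step of a named row was not measured, so the bound assumes that its step is no larger. Where the reads behind a value are fewer than its units, the precision of a low row is lower than its value implies.

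The identifiers of the rows repeat: 6113 label 1 row, 14451 label 2 or more, and 1 labels 274. No identifier of the 20564 (0) was found in the reference gene table at hand, assembly CAAS_Brap_v3.01, and the table itself gives no names. Gene lists fixed before the data were examined needed names or sequences and could not be matched, so no such list was tested. The sources used here do not say whether rows of 1 identifier are forms of 1 gene or different genes. Reads of near-identical rows can be divided between them by the estimation, so a row that changed while the sum of its identifier did not is then uncertain as a change of a gene. Where the rows are different genes, the sum mixes them and an unchanged sum says nothing against a change of 1 row. Every comparison was also made on sums per identifier. Across the libraries, 285 rows were at 0 everywhere and 7 were identical to an earlier row; they were left as deposited. No pair of libraries held identical values.

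The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling, the default filter on low rows (minimum count 10, total 15), robust dispersion and Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The 12 libraries of a tissue were fitted together for the treatment effect at each day, its change between days and the age difference in untreated plants, and all 24 libraries for the difference of the treatment effect between root and leaf. The tests, their libraries, the rule for naming rows and most alternatives were fixed before the data were examined. The rule took, of the rows past the threshold whose 3 SAB libraries all lay above or all below the 3 untreated ones with a mean of at least 5 CPM in 1 group, the 2 with the largest rise and the 2 with the largest fall, and, where 0 rows passed, the 3 with the smallest p. For the change between days the 2 higher and the 2 lower rows with the smallest adjusted p and a mean of at least 5 CPM in 1 group of day 18 were taken, and 3 of these in leaf and 3 in root are described. Standard errors are the log2 fold divided by the square root of the F statistic.

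The groups of rows were chosen after the data were examined. Leaf-enriched and root-enriched rows differed at least 4-fold between untreated leaf and untreated root in the same kind of test, at the day that was not being compared, and the 100 most abundant rows were taken from the same day, so that no library entered both the definition and the test. This does not hold for the age trend of untreated leaf or the check for leaf RNA in a root library of day 8. Their rows were chosen at day 8. Rows called in another comparison, rows whose identifiers begin with ATC or ATM, and rows of identifiers with 1 or with at least 20 rows were tested in the same family. Each group was tested against all other rows with camera (limma) on voom values with a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the groups of a comparison.

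Leaf and root libraries of the same treatment and replicate number deviated together at day 18: the correlation of their deviations from the group means across rows was 0.61 to 0.65 for the same number and -0.36 to -0.28 for other numbers, and every library correlated best with its own number. Deviations from a group mean cancel within each row, so the negative values follow from the high ones and are no separate baseline. The labels do not say that a number marks 1 plant, so this pairing comes from the data, and the difference between tissues at day 18 is given with and without these pairs as a block. At day 8 the same correlations were 0.07 to 0.18 in untreated and -0.03 to -0.01 in SAB plants, and no pairing was assumed.

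The test was checked on simulated data drawn from the means, spread and totals of the real libraries, with 200 rows changed. Units per read were drawn at random for each row. For leaf at day 18 edgeR recovered 3.12% of rows changed 2-fold and 20.4% of rows changed 4-fold over 43603 rows with 0 false calls. For root at day 8 it recovered 1.18% and 15.6% over 49027 rows with 6.25% of calls false. The simulated rows were independent and held none of the deviations that leaf and root libraries of the same number share. The 0 false calls therefore do not carry over to the real libraries. The spread used already holds counting error, which was added again, so the shares recovered can be too low. The share recovered also depends on how many rows are changed, which was not varied. Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, a filter at 1 CPM in 3 libraries, no filter, the replicate number as a block, other sets of libraries in the fit, a 2-fold minimum and each library left out in turn. Alternatives chosen after the data were seen were limma-trend with pseudocounts of 0.5 and 10 units, the pairing of leaf and root, the omission of root libraries that stood apart, and sums per identifier and left-out libraries for comparisons that had not been listed. Summaries and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.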

Results

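Transcript levels were measured in Choy-sum (Brassica rapa subsp. chinensis), a leafy vegetable, grown in pots of peat-moss soil from dressed or undressed seeds. The dressing was a consortium of 3 bacteria, Streptomyces, Agromyces and Bacillus, called SAB, and the untreated seeds had been soaked in a magnesium sulfate solution without bacteria. Whole leaves and whole roots were collected on day 8, at the true leaf stage, and on day 18, when plants were mature but had not begun to flower. Each of the 8 combinations of tissue, day and treatment had 3 independent biological replicates, which gave 24 libraries of polyadenylated RNA. The libraries held 28068078 to 37999455 estimated counts each, and 67.0% to 80.8% of the 66566 rows of the table were above 0 in a library. The rows carry 20564 distinct identifiers, of which 14451 label 2 or more rows, and the files used here do not pair identifiers with gene names. Rows are therefore named by identifier and by their order among the rows of that identifier, and levels are CPM, counts scaled to a common library total with TMM factors, as mean ± SD of n = 3 libraries. The consortium promotes growth of leafy vegetables, and the comparisons ask which transcript levels differed between SAB and untreated plants in each tissue and at each age.

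In leaves at day 8, 22 rows from 21 identifiers were higher in SAB plants and 0 were lower, of 46762 rows tested. Among them, row 1 of AT1G80840 stood at 67.7 ± 8.66 CPM in SAB leaves and 17.5 ± 3.00 CPM in untreated leaves, a log2 fold of 1.95 (SE 0.17, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.015). Row 1 of AT1G02400 stood at 14.2 ± 3.37 CPM against 3.94 ± 0.34 CPM, a log2 fold of 1.85 (SE 0.23, edgeR adjusted p = 0.0372). The 22 rows had a median log2 fold of 1.41, or 1.36 with the 1 row at 0 in all untreated libraries set to its lower bound, and 15 of them rose at least 2-fold. Of these 22 rows, 10 were root-enriched, meaning at least 4-fold higher in untreated root than in untreated leaf at day 18. The 2808 root-enriched rows tested had a median log2 fold of 0.11 (camera adjusted p = 0.0229, and adjusted p = 0.377 with an estimated correlation). The 5396 leaf-enriched rows held 0 calls and had a median of 0.07 (camera adjusted p = 0.0332, and adjusted p = 0.377 with an estimated correlation). The 100 most abundant rows of untreated leaf held 0 calls with a median of 0.16 (camera adjusted p = 1.12e-10, and adjusted p = 0.407 with an estimated correlation), and those of untreated root held 0 calls with a median of 0.05 (camera adjusted p = 0.132). In sums over all rows of an identifier, 69 identifiers were higher and 6 lower of 17706, and 15 of the 21 identifiers with a called row were among them. The count rested on single libraries: 0 rows passed without untreated replicate 1 or without SAB replicate 1, 1 without untreated replicate 3, 1 (a lower row) without SAB replicate 2, 4 without untreated replicate 2 and 35 without SAB replicate 3. Unadjusted p lay below 0.05 in 2916 rows where chance gives 2338, and DESeq2 called 698 rows.

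In leaves at day 18, 1350 rows were higher and 1210 lower in SAB plants, 5.47% of the 46762 rows tested and 2036 identifiers (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The leaf-enriched rows, at least 4-fold higher in untreated leaf than in untreated root at day 8, held more falls than rises: of 5334 tested, 575 fell and 4658 did not pass, with a median log2 fold of -0.22 (camera adjusted p = 4.18e-07, and adjusted p = 0.00581 with an estimated correlation). The size of this median rests on the TMM factors. Without scaling and without the 10 most abundant rows, centered library medians overlapped, at -0.08 to 0.04 in SAB and -0.02 to 0.1 in untreated leaves. Of the 3315 root-enriched rows tested, 236 rose and 24 fell, with a median of 0.41 (camera adjusted p = 3.98e-08, and adjusted p = 0.00144 with an estimated correlation). Of the 100 most abundant rows in untreated leaf, 42 fell and 0 rose, with a median of -0.56 (camera adjusted p = 5.02e-34, and adjusted p = 0.0459 with an estimated correlation). The 100 most abundant rows in untreated root held 5 that fell and 2 that rose, with a median of -0.26 (camera adjusted p = 0.000238, and adjusted p = 0.352 with an estimated correlation). Rows at least 16-fold higher in leaf than in root took 36.0% ± 0.781 of the counts in SAB leaves and 45.4% ± 2.15 in untreated leaves at day 18. The exact two-sided permutation test gave p = 0.1 for this share, the smallest p that 3 libraries against 3 allow.

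The rows that rose in leaves at day 18 had a median log2 fold of 1.18 and those that fell a median of -0.76. With the 45 rows at 0 in every untreated library and the 63 at 0 in every SAB library set to their lower bounds, these medians were 1.16 and -0.75. The rows with the largest fitted folds, named next, were such rows. Row 3 of AT1G73600 stood at 132 ± 38 CPM in SAB leaves and at 0 in untreated leaves, at least 88-fold higher (edgeR adjusted p = 0.000497). Row 1 of AT1G11840 stood at 114 ± 31.5 CPM against 0, at least 75.9-fold higher (edgeR adjusted p = 0.0306). Row 2 of AT1G76130 was at 0 in SAB leaves and at 37.1 ± 6.53 CPM in untreated leaves, at least 24.8-fold lower (edgeR adjusted p = 0.000793). Row 3 of AT1G77510 was at 0 against 16.8 ± 5.03 CPM, at least 11.2-fold lower (edgeR adjusted p = 0.000172). These bounds use 3 reads per library, or 1.5 CPM. Row 1 of AT1G11840, row 2 of AT1G76130 and row 3 of AT1G77510 were also called in the same direction in roots at day 18. Leaf and root libraries of the same number deviated together at that day. Rows at 0 in a whole group could differ by plant and not by treatment, which the design does not separate. Summed over all rows of the identifier, AT1G11840 was higher in SAB leaves (log2 fold 6.83, SE 1.22, edgeR adjusted p = 0.00512), and the other 3 sums were not called (edgeR adjusted p = 0.154 for AT1G73600, 0.265 for AT1G76130 and 0.262 for AT1G77510). Across all identifiers, 1401 sums were higher and 1154 lower, 14.4% of those tested, and they held 1617 of the 2036 identifiers with a called row. The number of called rows was 1407 without untreated replicate 1, the balance turned to 867 higher and 881 lower without untreated replicate 2 and to 1054 and 1099 without SAB replicate 3, and 1249 rows also reached a 2-fold change (836 higher and 413 lower).

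**Figure D1:**
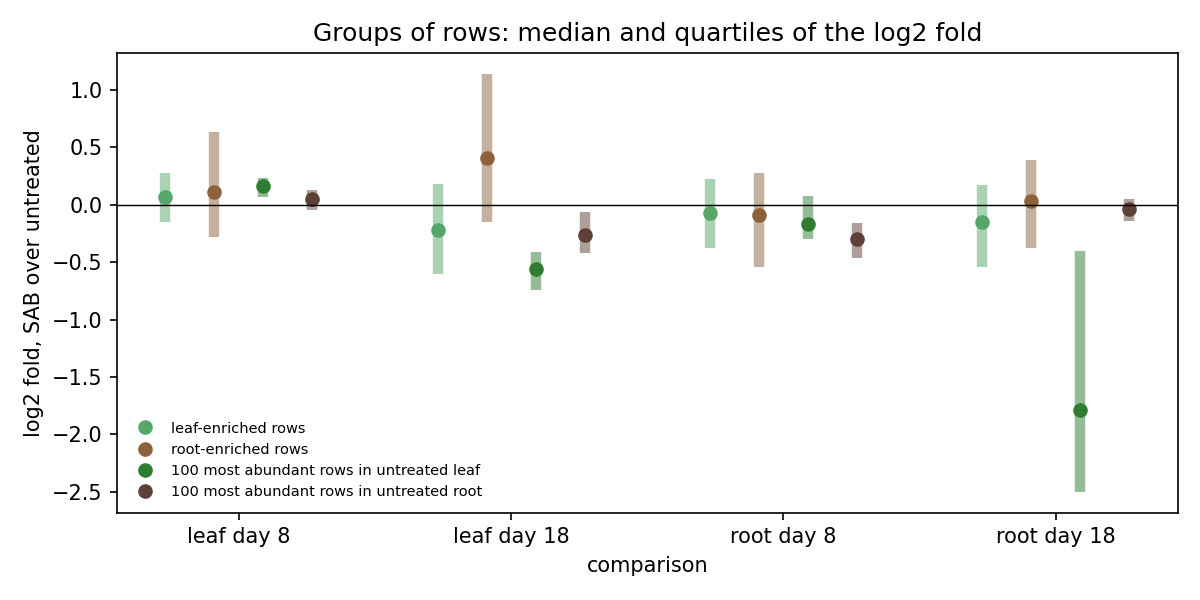
Median (points) and quartiles (bars) of the log2 fold of SAB over untreated in 4 groups of rows, for each tissue and day; the horizontal axis gives the comparison and the vertical axis the log2 fold. In leaf at day 18 the root-enriched rows have a median of 0.41 and the 100 most abundant leaf rows a median of -0.56, while the wide bar in root at day 18 belongs to leaf rows that are scarce in roots.

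In roots at day 8, 0 of 52257 rows passed the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.064. Unadjusted p lay below 0.05 in 3663 rows where chance gives 2613. DESeq2 called 928 rows (4934 at an unadjusted p below 0.05), of which 822 were lower in SAB roots, limma-voom called 10 (4117 unadjusted) and limma-trend called 38 (3921 unadjusted). The rows with the smallest p did not pass and lay near the detection floor. Row 2 of AT1G65280 stood at 2.71 ± 1.33 CPM in SAB roots and 0 in untreated roots, at least 2.05-fold higher (edgeR adjusted p = 0.0718). Row 1 of AT1G72520 stood at 0 against 2.12 ± 0.885 CPM, at least 1.61-fold lower (edgeR adjusted p = 0.0819). Row 2 of AT4G10040 was at 0 in SAB roots and at 0.965 ± 0.151 CPM in untreated roots, under the floor of 1.32 CPM, so no fold is given (edgeR adjusted p = 0.064). The root-enriched rows had a median log2 fold of -0.09 (camera adjusted p = 0.126), the leaf-enriched rows -0.07 (camera adjusted p = 0.44) and the 100 most abundant rows of untreated leaf -0.17 (camera adjusted p = 0.429). The 100 most abundant rows of untreated root had a median of -0.30 (camera adjusted p = 9.23e-08, and adjusted p = 0.466 with an estimated correlation). Sums per identifier gave 1 higher and 13 lower of 18973. Untreated replicate 3 stood apart from the other root libraries of day 8, with a mean rank correlation to its own group of 0.865 against 0.904 for each of the other 2. Without it 0 rows passed, without untreated replicate 2 there were 19, and without untreated replicate 1 or SAB replicate 3 there was 1.

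In roots at day 18, 64 rows were higher and 139 lower in SAB plants, 0.388% of 52257 rows and 188 identifiers (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 37 were at 0 in all untreated roots and 58 at 0 in all SAB roots. Row 1 of AT5G16130 stood at 81.2 ± 66.4 CPM in SAB roots and 0 in untreated roots, at least 56.8-fold higher (edgeR adjusted p = 0.0225). Row 2 of AT1G73030 stood at 67.0 ± 3.48 CPM against 0, at least 46.9-fold higher (edgeR adjusted p = 0.00318). Row 3 of AT1G77510, also at 0 in SAB leaves of this day, was at 0 in SAB roots and at 53.3 ± 10.9 CPM in untreated roots, at least 37.3-fold lower (edgeR adjusted p = 0.00398). Row 1 of AT5G15330 was at 0 against 52.2 ± 27.0 CPM, at least 36.5-fold lower (edgeR adjusted p = 0.00211). As in leaf, such rows could differ by plant and not by treatment. The sum over rows fell for AT5G15330 (log2 fold -1.08, SE 0.14, edgeR adjusted p = 0.00999), and was not called for AT5G16130, AT1G73030 or AT1G77510 (edgeR adjusted p = 0.99, 0.099 and 0.207). With rows at 0 set to their bounds (at 1.43 CPM), the median log2 fold was 1.87 among rows that rose and -1.64 among those that fell, leaving out 2 and 17 rows under the floor. Sums per identifier gave 38 higher and 107 lower, and included 66 of the 188 identifiers with a called row. The root-enriched rows (10 higher and 39 lower of 7331) had a median of 0.03 (camera adjusted p = 0.711), and the leaf-enriched rows (2 higher and 10 lower of 3559) a median of -0.15 (camera adjusted p = 0.0338, and adjusted p = 0.544 with an estimated correlation). The 100 most abundant rows of untreated leaf, scarce in roots, had a median of -1.79 with 95 of 100 below 0 and 1 called (camera adjusted p = 1.08e-10, and adjusted p = 0.544 with an estimated correlation). Strongly leaf-enriched rows took 0.662%, 0.585% and 1.02% of the counts in the untreated root libraries of day 18, and 0.503%, 0.567% and 0.55% in the SAB root libraries (exact two-sided permutation test, p = 0.1, the smallest p possible). The 100 most abundant rows of untreated root had a median of -0.04 with 1 higher and 1 lower (camera adjusted p = 0.291). The fit without untreated root replicate 3 of day 8 called 382 rows, limma-voom called 69, and leaving out any 1 library of day 18 gave 190 to 287.

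**Figure D2:**
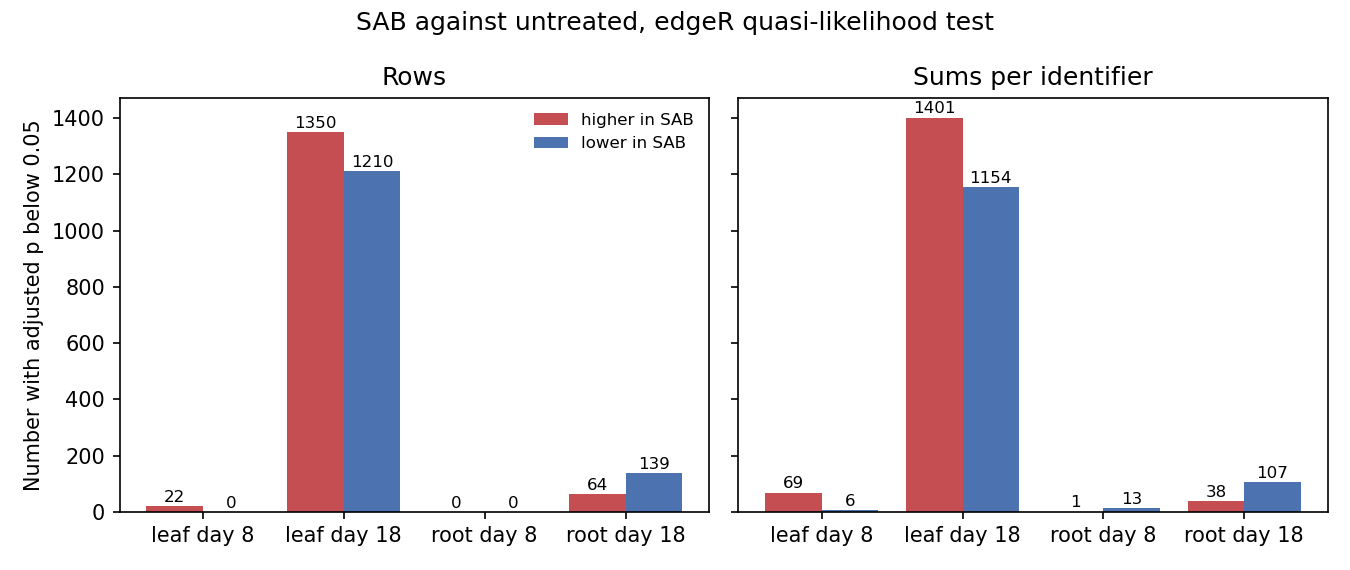
Number of table rows (left) and of identifiers after summing their rows (right) that were higher (red) or lower (blue) in SAB than in untreated plants, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment; the horizontal axis gives tissue and day. Leaves at day 18 have 1350 rows higher and 1210 lower, and roots at day 8 have 0.

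Of the 42792 rows tested in both tissues at day 18, 26 were called higher in both leaf and root, 44 were called lower in both and 0 were called in opposite directions. Leaf and root libraries of the same number deviated together at day 18 (correlations of 0.61 to 0.65), so independent lists are not the value without a treatment effect and no p is given for the overlap. Across rows, which are not independent replicates, the log2 folds of leaf and root at day 18 had a Spearman correlation of 0.479. The 9 other divisions of the same 6 numbered leaf and root pairs into 3 and 3 gave 0.399 to 0.453. Their 9 to 72 leaf calls and 19 to 94 root calls shared 2 to 34 in direction, and the 2469 leaf calls and 175 root calls of the treatment shared 70. The division that shared 34 had 72 leaf calls and 94 root calls, so the overlap is not evidence of a SAB effect common to both tissues. At day 8 the correlation between leaf and root was -0.116, against -0.0328 to 0.104 in the other 9 divisions.

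The question of whether the SAB effect changed with age was tested by the difference between the effects at day 18 and day 8. In leaves the effect was higher at day 18 for 62 rows and lower for 145, and in roots higher for 67 rows and lower for 62 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Row 4 of AT2G28000 stood at 45.0 ± 3.00 CPM in SAB leaves of day 18 and at 0 in untreated leaves (edgeR adjusted p of the difference = 4.07e-05), and row 2 of AT1G60420 at 11.3 ± 1.91 CPM against 0 (edgeR adjusted p = 0.00209). Both rows were also called higher in SAB roots at day 18, and rows at 0 in a whole group could differ by plant. Row 1 of AT5G47560 stood at 12.5 ± 1.70 CPM in SAB leaves of day 18 and 66.3 ± 10.8 CPM in untreated leaves, and its effect fell by 3.16 on the log2 scale between the days (SE 0.21, edgeR adjusted p = 0.00105). Its sum over rows gave -3.14 (edgeR adjusted p = 0.0147). The sum for AT1G60420 gave 0.97 (edgeR adjusted p = 0.037) and that for AT2G28000 was not called (edgeR adjusted p = 0.059). In roots, row 1 of AT3G51430 stood at 26.8 ± 3.86 CPM in SAB plants of day 18 and 2.73 ± 0.0283 CPM in untreated plants, and its effect was higher at day 18 by a log2 value of 3.52 (SE 0.29, edgeR adjusted p = 0.00334), with 2.48 for the sum over rows (edgeR adjusted p = 0.0311). Row 11 of AT1G77800 (23.3 ± 4.18 CPM in SAB roots of day 18 against 0, edgeR adjusted p = 0.00165) and row 3 of AT2G44060 (0.0202 ± 0.035 CPM against 117 ± 48 CPM, edgeR adjusted p = 0.00165) also differed between the days, but their sums were not called (edgeR adjusted p = 0.954 and 0.765). Sums per identifier gave 175 higher and 260 lower in leaf, and 156 higher and 47 lower in root. The balance in root was not stable: DESeq2 gave 1537 higher and 812 lower and the fit of all 24 libraries 235 and 92, but 56 and 121 were called without SAB replicate 3 of day 18. In leaves the count was 46 to 71 without any 1 of the 6 day 8 libraries and 324 without SAB replicate 3 of day 18. In roots it was 31, 35 and 36 without SAB replicates 1, 2 and 3 of day 8, 38 without untreated replicate 1 of day 8 and 343 without SAB replicate 1 of day 18; limma-voom called 66 in leaf and 7 in root.

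The 22 rows that were higher in SAB leaves at day 8 had fitted folds below 0 in roots of that day, which share no library with the leaf test. Their mean log2(CPM + 1) was taken on library totals without TMM factors, so levels of leaf and root are not compared. It was 4.36 ± 0.10 in SAB leaves and 3.19 ± 0.16 in untreated leaves, but 4.43 ± 0.31 in SAB roots and 5.41 ± 0.42 in untreated roots. In roots at day 8 all 22 fitted folds were negative, with a median of -1.22; 0 were called over all rows and 19 when adjusted over the list alone (camera adjusted p = 9.01e-23, and adjusted p = 0.168 with an estimated correlation). The difference between tissues was called for 21 of the 22, but it uses the leaf libraries by which these rows were chosen and is no independent evidence. At day 18 all 22 were positive in leaves, with a median of 1.74, and 21 were called higher, where independent lists of these sizes share 0.635. Rows are not independent replicates and both days come from 1 fit of the leaf libraries, so no p is given for this overlap. In roots at day 18, 20 of 22 were positive with a median of 0.57, and 0 were called (camera adjusted p = 1.88e-08, and adjusted p = 0.358 with an estimated correlation).

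**Figure D3:**
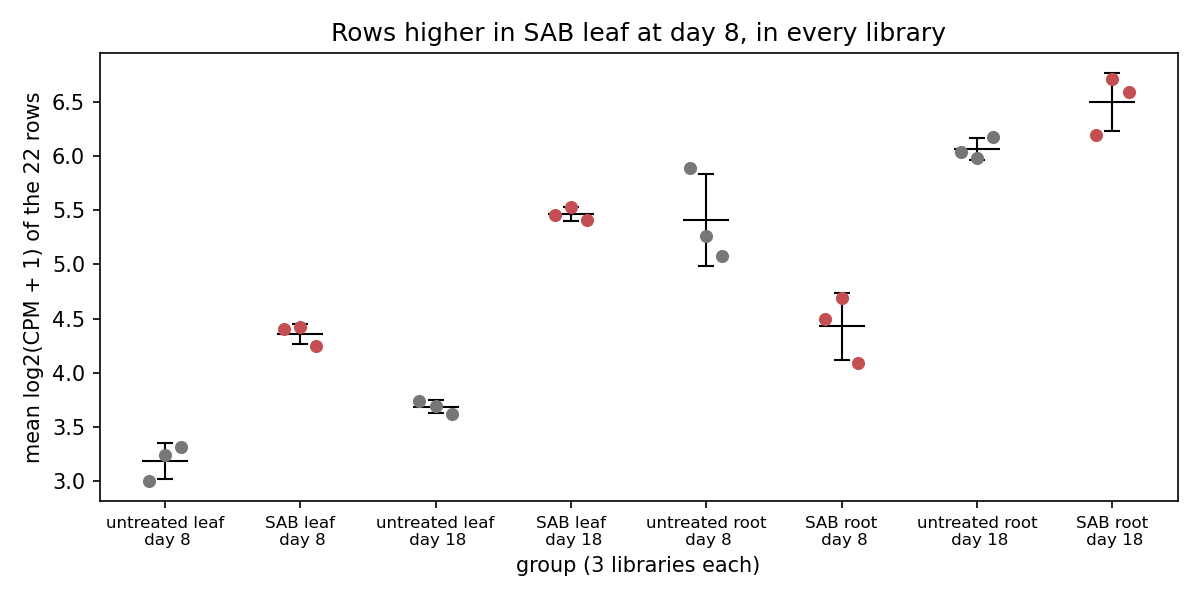
Mean log2(CPM + 1) of the 22 rows called higher in SAB leaf at day 8, for every library (points; grey untreated, red SAB), with the mean and SD of each group of 3 libraries; the horizontal axis gives the group. CPM are on library totals without TMM factors. SAB leaves lie above untreated leaves at both ages, and at day 8 the 3 SAB roots (mean 4.43) lie below the 3 untreated roots (mean 5.41).

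Over all rows at day 8, the SAB effect was lower in root than in leaf for 419 rows and higher for 26, of 57445 tested in the fit of all 24 libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). These rows were chosen by the difference itself, so their opposite signs in the tissues at day 8 follow from the choice, and 0 of the 419 were called in root at day 8 alone. At day 18, 263 of these rows were higher in SAB leaves where independent lists give 12, 3 were lower, and the median log2 fold of the set in leaf was 1.37. Rows are not independent replicates and both fits hold the same leaf libraries, so no p is given for this overlap. Of the 419, 372 were positive in roots at day 18, with a median of 0.48, and 3 were called higher and 2 lower. The count of 445 was 242 without SAB root replicate 3, 271 without untreated leaf replicate 1, 286 without untreated root replicate 1 and 292 without SAB root replicate 1, and it was 504 without both untreated root replicate 3 of day 8 and SAB root replicate 3 of day 18. The first of these had 251 rows at 0 that were on in the other 2 libraries of its group, against 7 to 36 in the other roots of day 8, and the second had 84, against 243 to 292 in the other roots of day 18. At day 18 the SAB effect was higher in root than in leaf for 38 rows and lower for 55. With leaf and root libraries of the same number treated as a pair, 10 were higher and 14 lower, and 15 of the 93 were shared. Without 1 library the day 18 count was 37 to 52 for each untreated root, 44 to 59 for each SAB root, 49 and 150 for untreated leaf replicates 2 and 3, and 40 and 141 for SAB leaf replicates 1 and 3.

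**Figure D4:**
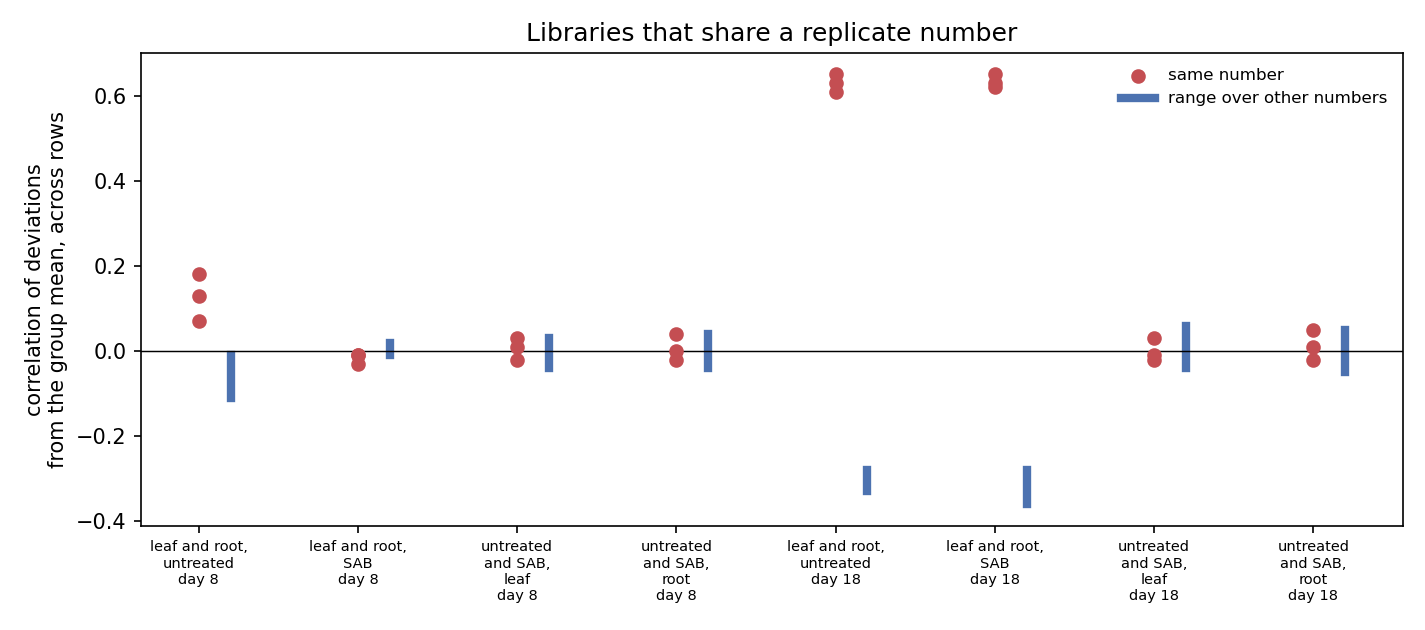
Correlation across rows of the deviations of 2 libraries from their group means (vertical axis), for libraries with the same replicate number (red points) and the range over pairs with different numbers (blue bars); the horizontal axis gives the groups paired. Leaf and root libraries of the same number at day 18 reach 0.61 to 0.65, while untreated and SAB libraries of the same number stay between -0.02 and 0.05.

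In both tissues more rows were called between the ages of untreated plants than between treatments at either day. In untreated leaves 4675 rows were higher and 5027 lower at day 18 than at day 8, 20.7% of those tested, and in untreated roots 1158 were higher and 1718 lower, or 5.50% (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Of these, 5751 of the leaf rows and 1865 of the root rows changed at least 2-fold. Sums per identifier gave 7184 in leaf and 3126 in root. The root count was 1844 and 1753 without untreated replicates 1 and 2 of day 8, and 1673, 1434 and 1488 without untreated replicates 1, 2 and 3 of day 18.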

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

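The tests of differences between days and between tissues were planned; the count of splits that keep leaf and root pairs together was chosen after the result was seen. The SAB effect differed between day 8 and day 18 for 207 rows in leaf and 129 rows in root, and between root and leaf for 445 rows at day 8 and 93 rows at day 18 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). Other splits of the same libraries bear on whether chance groups would do as well. In leaf, 1 of 40 splits, the real one, called as many as 207 rows for the change between days and the highest other called 43. In root, 1 of 40 called as many as 129 and the highest other called 76. Both shares are the smallest that 40 splits allow. The other splits mix SAB and untreated libraries, so they bear on the absence of any SAB effect. They do not show what chance gives where the effect is equal at both days, so chance is not excluded. For the difference between tissues at day 8, 1 of 25 splits called as many as 445 rows and the highest other called 6. The same limit holds. In addition, 9 of the other splits were set to keep leaf and root libraries of a number together and were not drawn at random. At day 18, 2 of 25 splits called as many as 93 rows and the highest other called 195, so chance cannot be excluded by this count. That highest split put the leaf and root libraries of each number on opposite sides, which points to the structure of the pairs; of the splits that kept each pair together, as the treatment does, the 9 others called at most 5 rows.

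Among the named rows, the difference of the SAB effect between root and leaf at day 8 was a log2 value of -4.16 for row 1 of AT1G80840 and -3.21 for row 1 of AT1G02400, rows that were chosen for their rise in the same leaf libraries. The change of the effect between days in leaf was fitted at 14.19 for row 3 of AT1G73600, -14.4 for row 2 of AT1G76130 and -11.33 for row 3 of AT1G77510. In root it was fitted at 15.49 for row 1 of AT5G16130, 13.89 for row 2 of AT1G73030, -13.67 for row 3 of AT1G77510 and -13.98 for row 1 of AT5G15330. For the rows that did not pass in root at day 8, the fitted change between days was 8.28 for row 2 of AT4G10040, -9.23 for row 2 of AT1G65280 and 10.54 for row 1 of AT1G72520, and the last had a fitted difference between tissues at day 8 of -17.21. Apart from AT1G80840 and AT1G02400, each of these rows was at 0 in all libraries of a group, so the fitted values depend on the prior count and are neither sizes nor bounds.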

How the results depend on the processing

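The limma-trend fits, the pairing of leaf and root, the omission of root libraries, and for the tissue differences also the sums and left-out libraries, were chosen after the result was seen. Of the counts of called rows, 103 lay within 1.5 times the reported count and 86 did not; the cause was not tested unless the setting itself gives it. The balance of higher and lower calls turned in some of them: leaf at day 18 gave 867 higher and 881 lower without untreated replicate 2 and 1054 and 1099 without SAB replicate 3, and leaf at day 8 gave 0 and 1 without SAB replicate 2. For the change between days in root, more rows were lower than higher with limma-voom and without untreated replicate 1 or SAB replicates 1 or 3 of day 8, or SAB replicates 2 or 3 of day 18 (56 and 121 for the last). For the tissue difference at day 18, more were higher than lower with the replicate number as a block and without untreated leaf replicate 2, untreated root replicate 3 or SAB root replicates 1 or 2. Among named rows 341 alternatives kept their side of the threshold, 48 lost it and 12 gained it; among row groups 386 kept it, 26 lost it and 11 gained it. DESeq2 called 698 rows in leaf at day 8, 5829 in leaf at day 18, 928 in root at day 8, 2123 in root at day 18, 2474 and 2349 for the change between days in leaf and root, 1575 and 1022 for the tissue difference at day 8 and day 18, and 7222 for age in root; it shared 2557 of the 2560 calls of leaf at day 18 and all 203 of root at day 18. Limma-voom called 10 in root at day 8, 69 in root at day 18 (60 shared), 66 for the change between days in leaf and 7 in root. Limma-trend with pseudocounts of 0.5 and 10 called 103 and 97 in leaf at day 8, 38 and 29 in root at day 8, and 193 and 241 for the tissue difference at day 18; with 0.5 it called 207 for the change in root. RLE scaling gave 34 in leaf at day 8, including all 22, and 2461 in leaf at day 18 (2448 shared). Sums per identifier gave 75 in leaf at day 8, 14 in root at day 8, 435 and 203 for the change in leaf and root, and 201 for the tissue difference at day 18. A 2-fold minimum left 1249 in leaf at day 18, 5751 for age in leaf and 1865 for age in root. All 24 libraries in 1 fit gave 75 in leaf at day 8, 66 in root at day 8, and 353 and 327 for the change in leaf and root; the 6 libraries compared alone, with fewer degrees of freedom, gave 0, 234 and 17 in leaf at day 8, leaf at day 18 and root at day 18. Leaving out 1 library gave 0 to 35 in leaf at day 8, 1407 to 2153 in leaf at day 18, 0 to 19 in root at day 8, 190 to 287 in root at day 18, 46 to 324 and 31 to 343 for the change in leaf and root, 242 to 540 and 37 to 150 for the tissue difference at day 8 and day 18, 6856 to 8754 for age in leaf and 1434 to 3819 for age in root. Without untreated root replicate 3 of day 8, root at day 18 gave 382. Untreated and SAB libraries of the same number correlated at -0.02 to 0.05 across rows, and across sums per identifier at -0.05 to 0.11 at day 8 and -0.01 to 0.16 at day 18 (0.16, 0 and 0.15 in root). Not every pair exceeded 0.1 and not every library correlated best with its own number, so the numbers were not taken to pair the treatments; the replicate number as a block gave 0 in leaf at day 8, 768 in leaf at day 18, 0 in root at day 18, 1 and 0 for the change in leaf and root, and 174 and 2 for the tissue difference at day 8 and day 18. The pairing of leaf and root as a block gave 24 for the tissue difference at day 18 and 430 at day 8 (316 shared). Depth limits rows under the floor of 3 reads per library, where no fold is given.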

Other observations

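The tests of row groups, of root RNA, of abundant rows, of the age trend, of the pairs of leaf and root and of the shift in read length units were chosen after the result was seen; those of leaf RNA and splits of the libraries were fixed before it. The rows higher in SAB leaves at day 18 already leaned the same way in leaves at day 8: 1060 of 1350 were positive, with a median log2 fold of 0.29, 21 were called, and 336 were higher and 6 lower when adjusted over the list alone (camera adjusted p = 1.86e-29, and adjusted p = 0.0013 with an estimated correlation). In roots at day 8 the same rows had a median of -0.44 with 1086 of 1329 negative (camera adjusted p = 1.72e-23, and adjusted p = 0.179 with an estimated correlation). The rows lower in SAB leaves at day 18 had a median of 0.01 in leaves at day 8 (camera adjusted p = 0.78) and of 0.01 in roots at day 8 (camera adjusted p = 0.595). They had in roots at day 18 a median of -0.29, or -0.28 with rows at 0 at their bounds, but leaf and root libraries of the same number deviated together at day 18, so a fall can follow from the choice of rows in leaf and no p is given. The rows whose identifiers begin with ATC had a median of 0.38 in SAB leaves at day 8 (camera adjusted p = 5.27e-06, and adjusted p = 0.377 with an estimated correlation) and of -0.13 at day 18 (camera adjusted p = 0.123), and those beginning with ATM had medians of 0.54 and -0.08 (camera adjusted p = 0.103 and 0.726). Rows of identifiers with at least 20 rows had medians of -0.03 and -0.06 in leaves at day 8 and day 18 (camera adjusted p = 0.78 and 0.726) and rows of identifiers with 1 row had 0.01 and -0.02 (camera adjusted p = 0.512 and 0.726).

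The most abundant row of untreated leaves at day 8 took 4.96% ± 0.159 of the counts there and 4.70% ± 0.859 in SAB leaves, and at day 18 it took 3.22% ± 0.153 in untreated leaves and 2.1% ± 0.145 in SAB leaves (n = 3 each, no test). The 10 most abundant rows of each library together took 11.1% ± 0.630 in untreated and 7.81% ± 0.414 in SAB leaves at day 18. Of the called rows at 0 in a whole group at day 18, most were above 0 in the same treatment at day 8. In leaf, 58 of the 63 rows at 0 in SAB plants were above 0 in all 3 SAB libraries of day 8, and 49 of the 63 were also at 0 in all 3 SAB roots of day 18. Of the 45 rows at 0 in untreated leaves, 30 were also at 0 in all untreated roots. In root, all 37 rows at 0 in untreated and all 58 at 0 in SAB plants were above 0 in every library of that treatment at day 8, and 34 and 48 were also at 0 in the leaves of day 18. The sums of the identifiers that hold such rows stayed within 2-fold between treatments for 75.6% and 79.6% in leaf and 88.9% and 79.6% in root (rows at 0 in untreated and in SAB plants). Of these sums 18 of 41 and 25 of 54 were called in leaf and 2 of 36 and 12 of 54 in root (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), but each holds the row by which its identifier was chosen, so neither value shows whether the rest of the identifier changed.

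Leaf-enriched rows were lower and root-enriched rows higher in SAB leaves at day 18. Root RNA in the SAB leaf samples would raise every abundant root row, but the 100 root-enriched rows most abundant in root gained a median of 0.592% of their root level (bootstrap interval over rows 0.00123 to 2.72), and 60 of them gained. The interval leaves out variation among libraries. Mixing root RNA into untreated leaf would need 8.02% to give the median of all root-enriched rows, 12.1% for that of all leaf-enriched rows and 20.7% for the fall of the counts in strongly leaf-enriched rows, which argues against this explanation. A few abundant rows taking most of the counts would scale all other rows of a library by 1 factor and leave the distance between these groups as it was. Without scaling and without the 10 most abundant rows, the median of root-enriched rows minus that of leaf-enriched rows was 0.26 to 0.4 on the log2 scale in SAB leaves and -0.38 to -0.18 in untreated leaves. This difference of 0.64 argues against 1 factor as the whole cause of the distance. It came mostly from root-enriched rows, with medians of 0.27 to 0.44 in SAB and -0.35 to -0.13 in untreated leaves. Those of leaf-enriched rows overlapped, at -0.08 to 0.04 and -0.02 to 0.1, so the distance does not show that leaf-enriched rows fell. A fit without the 10 most abundant rows called 566 leaf-enriched rows lower (575 with them), but leaving them out hardly moved any value and decides nothing. A different position of SAB leaves on the trend from day 8 to day 18 is argued against as the whole cause of the lower level of leaf-enriched rows. These rows took 53.2% ± 1.28 of the counts in untreated leaves at day 8 and 53.5% ± 2.32 at day 18, against 44.3% ± 0.548 in SAB leaves at day 18. They were chosen in untreated plants of day 8, which can raise their share there. SAB leaves at day 8, which did not enter the choice, stood at 54.2% ± 1.18. Ages beyond day 18 were not sampled. Across leaf-enriched rows the SAB fold correlated with the age fold of untreated leaf at 0.099 to 0.218 in the cross-fitted pairs, so a part that goes with age stays open. For root-enriched rows this position cannot be told apart from a response to the treatment. Their share was 1.04% ± 0.0997 and 2.29% ± 0.0899 in untreated leaves of the 2 ages and 3.85% ± 0.246 in SAB leaves at day 18. The choice of rows at day 8 can lower the first of these values and so widen the step with age. SAB leaves at day 8 stood at 1.29% ± 0.0583. The age folds of both groups use the same untreated leaves of day 8. The correlation of their SAB fold with the age fold of untreated leaf had a median of 0.185 over 3 cross-fitted pairs, with a lowest value of 0.06 and a highest of 0.226. A response of leaves to the consortium may account for the pattern and stays open as an untested hypothesis.

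Leaf and root libraries of the same number deviated together at day 18 and shared rows at 0. Of the rows off in 1 library, only those at 5 CPM or more in a library of the other tissue were counted. A median of 90.8% of these were also at 0 in the partner of the other tissue, against at most 1% in other numbers. The value was 18.5% for SAB leaf replicate 3 and 71.2% to 96.6% for the other libraries. A library batch per number that both treatments share is argued against as the whole cause: untreated and SAB libraries of the same number correlated at most at 0.05 across rows, and across sums per identifier at most at 0.16, where leaf and root of the same number reached 0.37 to 0.45. A smaller shared part in the sums, and a batch shared by leaf and root of 1 treatment alone, stay open. Leaf and root taken from 1 plant, with plants that differ in the rows they carry, is a candidate explanation that the 90.8% allows, with 1 pair apart: SAB root replicate 3 had 84 rows off against 243 to 292 in the other roots of day 18, and its leaf partner is the one with 18.5%, for which no explanation was tested. Reads moved between rows of 1 identifier, as with sequence variants that match another row better, is also a candidate explanation. The sums of the identifiers with a row off stayed within 2-fold in a median of 87.3%, but a row that is a small part of its sum also gives this. In each library of day 18 the median log2 difference of these sums was negative (-0.48 to -0.23), and in leaf libraries of day 8 it was -0.37 to -0.2. Each sum holds the row chosen for being at 0. Reads moved to a row where 1 read is worth fewer units would also lower it, so this fall decides nothing. If either candidate holds, rows at 0 in 3 plants of a treatment could differ by plant and not by treatment, which the design does not separate.

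Untreated root replicate 3 of day 8 stood apart, with 251 rows off that were on in the other 2 libraries of its group, against 7 to 36 in the other root libraries of day 8. Rows at least 16-fold higher in leaf took 0.539% of its counts and up to 0.671% in the other root libraries of day 8, so no excess of leaf RNA was seen. These rows were chosen in a test that held this library as an untreated root, which can lower its share. Leaf RNA is therefore not excluded. RNA of fewer plants cannot be decided. The sums of the identifiers with a row off stayed within 2-fold in 45.6% of cases, below the 80.0% to 93.4% of the libraries of day 18. Whether rows off at day 18 come from single plants is itself open, so those libraries do not show what fewer plants would give. A shift of its reads towards shorter features is a candidate explanation that remains open: 1 read was worth 0.823 of the mean over libraries, against 0.909 to 1.136 elsewhere. No biological explanation was tested for this library.

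For the comparisons of 3 libraries with 3, the 10 possible splits cannot give a share under 0.05. In leaf at day 8 the real split called 22 rows and the highest other 2, with 1 of 10 as large; in leaf at day 18 the values were 2560 and 72, with 1 of 10. In root at day 8 the real split called 0 rows and so did each of the 10. In root at day 18 the real split called 203 and the highest other 49.8% as many, with 1 of 10. Splits that mix the treatments thus also passed many rows there, so single calls of that comparison may not reflect treatment. For age in untreated plants the real split called 9702 rows in leaf against 3 at most, and 2876 in root against 4 at most, with 1 of 10 in each.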
